A study of Mus musculus with 18 samples.

How the data were processed

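RNA from the thalamus of wild-type mice was measured in 18 libraries, 6 each from a control group given saline, a model group given a treatment labelled Coll IV, and an intervene group given Coll IV and remodelin. The expansion of Coll IV is not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol, captured with oligo(dT) beads and fragmented before sequencing. The labels give no time after injury, sex, litter, day or sequencing batch, and do not say whether the libraries are strand-specific.

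The authors deposited a table of raw counts and a table of FPKM for 50559 genes in all 18 libraries. Per the submitters' processing notes, reads were aligned with HISAT2, counted with featureCounts and referred to GRCm39; versions are not given in the sources used here. The deposited FPKM values equal the count divided by a gene length and by the column's total. This was tested on the 18117 genes counted in every library, of which 18117 gave the same whole length in all libraries at a relative tolerance of 1e-06. FPKM therefore adds no independent measurement and was used only as an alternative. Gene symbols are those of the deposited count table. Reads shared by paralogs, pseudogenes, repeated RNA genes or overlapping genes can be divided differently between the copies, so values of such genes are uncertain. No coordinates were used.

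The smallest chi-square per degree of freedom between 2 libraries of a group was 11.4 over genes with at least 20 counts in the pair. No library thus repeated another of its own group within sampling noise. Totals ranged from 28481225 to 118461420 counts, with control replicate 1 the highest, control replicate 5 at 56878946 and the other 16 libraries at 36361681 or fewer. The labels number separate samples within each group but do not state that each is a separate animal, so the p-values measure the spread between these samples. In 18 of 18 libraries the Y-linked genes had more counts than Xist.

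Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust estimation, on all 18 libraries in 1 fit with a mean per group and no covariate. Scaling was by TMM after filterByExpr, which left 18452 genes. P-values were adjusted by the Benjamini-Hochberg method over those genes, with a threshold of 0.05 and no fold minimum. CPM are TMM-scaled, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. Folds of genes with almost no counts in a group depend on edgeR's prior count.

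Before the data were examined, 45 gene lists with 689 genes were fixed for cell types, brain regions and pathways; 636 of the genes passed the filter. A list's score in a library is the mean log2 CPM of its measured members with a prior count of 2. The 44 lists other than the sex-linked genes were tested with a two-sided exact permutation test over the 924 arrangements of 12 libraries, with Benjamini-Hochberg adjustment over the 44 lists. The smallest p this test can give is 0.00216. Members were counted over all genes tested and adjusted over the list alone. Genes were named by a rule also fixed then: Nat10 in each comparison, the 8 largest called changes in each direction with a mean CPM of at least 1 in the higher group and a symbol that is not a predicted-gene, clone or pseudogene name, or the 5 genes of lowest p in a direction where none was called, and up to 4 members of each list by p. Not every name the rule gives is printed. Shox2, Prss12 and Lars2 come from the same rule applied within libraries 4 to 6, a comparison added later. Tcf7l2, Slc17a7, Ttr, and Hmox1 in model against control, were named after their values were seen, as were genes called in fewer than 10 cases by an alternative.

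On simulated counts with the real means, library sizes and dispersions, 200 of 18452 genes were changed, drawn from those with a mean CPM of at least 1. There the test of model against control recovered 70.1% of changes of 2-fold, 98.5% of 4-fold and 100% of 8-fold. For intervene against model it recovered 68.7%, 91.0% and 98.5%, and for intervene against control 82.1%, 89.6% and 98.5%. In those simulations the share of calls that were false was 4.79%, 1.15% and 2.70%. The simulated libraries were drawn independently, without differences that many genes share, such as those by replicate number described below. These shares therefore need not hold for the real data or for genes of lower CPM. The permutation test gave a p under 0.05 in 4.75% of 2000 unchanged simulated lists.

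Libraries with the same replicate number deviated together in control and model: the correlation of their deviations from the group means, across genes, was 0.18 to 0.63 and over 0.1 in 6 of 6 pairs, although only 4 of 12 libraries correlated best with their own number. The rule used here, over 0.1 in all 6 pairs, is thus met for control and model. Libraries numbered 1 to 3, and those numbered 4 to 6, also deviate together whatever their number, which can meet the rule. It therefore does not show that the numbers pair libraries, and the labels do not say what a number marks. Between intervene and model 5 of 6 pairs were over 0.1 and between intervene and control 3 of 6, with the lowest at -0.13 and -0.14. The rule is thus not met for intervene libraries. The other settings tried were DESeq2 1.42.0, limma 3.58.1 (voom with quality weights), 3 other scalings, 2 other filters, only the 12 libraries compared, the replicate number as a block, 1 surrogate variable from sva 3.50.0, FPKM with a pseudocount of 0.1 or 1, removal of haemoglobin and mitochondrial genes, a log2 fold minimum of 1, each library left out, and for lists also camera, fry and the median. Comparisons within libraries numbered 1 to 3 and 4 to 6, with that division as a covariate or permuted within it, were added after the first principal component had been seen. Whether the intervene minus model difference of a list score changed between these sets was tested by permuting the residuals of the additive fit of group and set 100000 times, adjusted over the 44 lists, also after the results had been seen.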

Results

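Gene expression was measured by RNA-seq in 18 libraries of mouse thalamus in 3 groups of 6, named control (saline), model (Coll IV) and intervene (Coll IV and remodelin). Remodelin is an inhibitor of the acetyltransferase NAT10, and the series concerns its effect on inflammation-related genes after thalamic haemorrhage. Collagenase is commonly injected to cause brain haemorrhage, but the labels do not expand Coll IV. Libraries held 28481225 to 118461420 counts and 23648 to 28832 genes with at least 1 count. Mitochondrial genes took 7.40 to 17.7% of counts and haemoglobin genes 0.0117 to 0.0485%.

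Markers of brain regions differed strongly between libraries of the same group. Taken over control and model, libraries numbered 4 to 6 had fewer transcripts of thalamic neurons, habenula, hypothalamus, choroid plexus and ependyma than libraries numbered 1 to 3, and more of cortex. Tcf7l2, a transcription factor of thalamic neurons, averaged 101 ± 1.85 CPM (SD, n = 3) in controls 1 to 3 and 4.51 ± 0.632 in controls 4 to 6. In model libraries it averaged 90.2 ± 47.9 and 7.78 ± 2.87 CPM, and in intervene libraries 82.8 ± 19.3 and 39.4 ± 8.27 CPM. Slc17a7, the vesicular glutamate transporter of cortical and hippocampal neurons, went the other way, at 245 ± 273 and 1626 ± 43.4 CPM in controls, 571 ± 252 and 1177 ± 81.7 in model and 475 ± 211 and 748 ± 246 in intervene. Over control and model together, 14 of 18 thalamic list members were lower in libraries 4 to 6 and 0 higher, 14 of 15 choroid plexus members were lower, and 10 of 16 hippocampus and cortex members were higher and 1 lower, by edgeR at an adjusted p under 0.05. Within control alone 9 of these 16 were higher and 1 lower, and within model alone 1 was higher and 1 lower. Within intervene few members of the region lists were called: 1 of 18 thalamic members was lower in libraries 4 to 6 and 0 higher (median log2 difference -0.02), 1 of 16 hippocampus and cortex members was higher and 0 lower (median 0.68, against 0.83 in model). Of 8 habenula, 14 hypothalamus and 15 choroid plexus members there 0 were called (medians 0.13, 1.02 and -0.71). In all, 4215 genes were higher and 4514 lower in libraries 4 to 6 of control and model, and 1431 higher and 1321 lower in those of intervene. The first principal component held 44% of the variance and parted the libraries by these numbers within each group. The division was noticed in the data and is not stated in the labels, so the comparisons were also made within it.

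**Figure D1:**
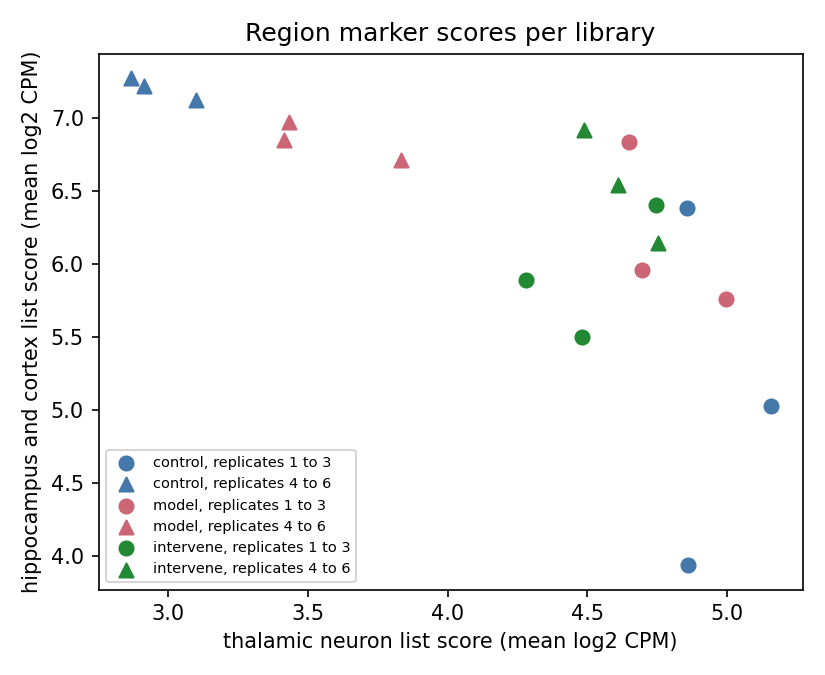
Score of the thalamic neuron list (x axis, mean log2 CPM) against that of the hippocampus and cortex list (y axis, mean log2 CPM), 1 point per library, coloured by group, circles for replicates 1 to 3 and triangles for 4 to 6. Control and model triangles, with thalamic scores of 2.87 to 3.83, lie to the left of all other libraries.

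Nat10, the target of remodelin, was expressed at the same level in the 3 groups within the spread between libraries: 17.1 ± 1.59 CPM in control, 16.4 ± 1.70 in model and 16.2 ± 1.05 in intervene (SD, n = 6 each). Its log2 fold change was -0.06 ± 0.08 (SE) for model against control, -0.02 ± 0.08 for intervene against model and -0.08 ± 0.08 for intervene against control, with edgeR adjusted p of 1, 0.992 and 0.780. The inhibitor acts on the protein, which was not measured.

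The comparison of model with control asks what the Coll IV treatment changed. No gene or list passed the test, and of the 44 list scores the widest difference was in choroid plexus markers. Ttr, the transthyretin gene that the choroid plexus expresses at a very high level, averaged 2187 ± 2440 CPM in model and 131 ± 275 in control. Most of the control mean came from replicate 1, with 688 CPM and the next control at 70.2. By set, model had 4314 ± 1130 and 60.4 ± 28.2 CPM and control 261 ± 371 and 0.415 ± 0.167. Aqp1 averaged 4.74 ± 4.31 against 0.724 ± 0.646 CPM, and Kcne2 8.89 ± 9.56 against 0.782 ± 1.23, where control replicate 1 had 3.26 and the next 0.576. All 15 measured choroid plexus members had a positive fold change, 0 passed over all genes, and 8 passed adjusted over the list alone. The list's score was 2.35 ± 2.07 in model and -0.09 ± 1.74 in control (exact permutation p = 0.0606, adjusted p = 0.524), a difference of 2.88 among libraries 1 to 3 and 2.01 among libraries 4 to 6. In each set all model libraries lay above all control libraries. The score was therefore higher in model in 6 of 6 pairs of equal replicate number, as in any pairing within the sets. With labels permuted within the 2 sets the p was 0.005, the smallest possible there (adjusted p = 0.11). The ependymal score went with it, at 2.85 ± 0.801 in model and 1.58 ± 1.54 in control, with 12 of 12 members positive, a difference of 0.70 among libraries 1 to 3 and 1.85 among libraries 4 to 6 and the same p within the sets (over all 12 libraries exact permutation p = 0.0931, adjusted p = 0.585).

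Among injury genes, Lgals3, a galectin of reactive microglia, was 3.60 ± 3.17 CPM in model and 1.18 ± 0.729 in control (log2 fold change 1.60 ± 0.52, adjusted p = 1), with model replicate 1 at 9.69 CPM. Hmox1, which degrades haem, was 11.2 ± 8.23 against 7.28 ± 1.48 CPM, with 6.20 ± 0.893 against 6.75 ± 0.837 in libraries 1 to 3 and 16.2 ± 9.68 against 7.82 ± 1.99 in libraries 4 to 6. Its higher mean thus came from the latter alone. Ftl1, an iron storage subunit, was 501 ± 33.0 against 420 ± 45.7. The complement score was 2.99 ± 0.235 against 2.71 ± 0.113, the haem, iron and oxidative defence score 5.01 ± 0.0620 against 4.90 ± 0.08, and the cytokine and chemokine score -0.09 ± 0.41 against -0.60 ± 0.28. Their exact permutation p values were 0.0173, 0.0216 and 0.0390, and the adjusted p values 0.476, 0.476 and 0.524. Their differences were 0.33, 0.08 and 0.09 among libraries 1 to 3 and 0.23, 0.14 and 0.91 among libraries 4 to 6. The erythroid score, a measure of blood, was 4.45 ± 0.612 against 4.27 ± 0.523 (exact permutation p = 0.619), a difference of 0.22 among libraries 1 to 3 and 0.14 among libraries 4 to 6. Reactive astrocytes, with 2.27 ± 0.406 against 1.95 ± 0.293, and the interferon response, with 1.51 ± 0.269 against 1.54 ± 0.326, did not pass either (adjusted p = 0.714 and 0.974). Their differences were 0.45 and 0.12 among libraries 1 to 3 and 0.19 and -0.19 among libraries 4 to 6.

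Of the genes with the lowest p, Fpgs was 4.68 ± 0.626 CPM in model and 3.33 ± 0.440 in control and Tgfbr2, a receptor for transforming growth factor beta, 14.9 ± 2.29 against 10.8 ± 1.41. P2rx3 was 1.81 ± 0.365 against 2.59 ± 0.225 and Hsph1, a heat shock protein, 282 ± 33.5 against 346 ± 64.5; none of the 4 passed (adjusted p = 1). With edgeR, 0 of 18452 genes passed in either direction, 310 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 2, both predicted genes that were lower in model (Gm5451 and Gm8355). Within libraries 1 to 3 and within libraries 4 to 6, edgeR also called 0 genes, with 1075 and 1876 at an unadjusted p under 0.05.

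The comparison of intervene with model asks what remodelin changed in treated animals. Interferon-induced, reactive astrocyte and chemokine genes had higher means in intervene, but no gene or list passed. For lists this was in part fixed by the design, since 1 list alone at the smallest possible p has an adjusted p of 0.0952 over the 44. Timp1, a metalloprotease inhibitor made by reactive astrocytes, was 2.06 ± 0.727 CPM in intervene and 0.683 ± 0.339 in model (log2 fold change 1.59 ± 0.32, adjusted p = 0.988). DESeq2 called it, with an adjusted p of 0.0205. Cd44, a matrix receptor, was 6.42 ± 1.86 against 2.76 ± 1.21 CPM, and 20 of 20 measured reactive astrocyte members had a positive fold change, 0 passing over all genes and 8 adjusted over the list alone. Their score was 3.12 ± 0.297 against 2.27 ± 0.406 (exact permutation p = 0.00433, adjusted p = 0.0952), a difference of 0.35 among libraries 1 to 3 and 1.34 among libraries 4 to 6. This change of 0.99 between the sets passed a permutation test (adjusted p = 0.0442). With an estimated correlation camera called this list (adjusted p = 0.0434). The homeostatic astrocyte score was higher as well, by 0.20 (exact permutation p = 0.0433, adjusted p = 0.328), with 13 of 16 members positive. Its difference was 0.112 among libraries 1 to 3 and 0.285 among libraries 4 to 6. A larger share of astrocytes alone would raise both lists alike, if both lists measure only astrocytes. Under that premise, which was not tested, the rises of 1.34 and 0.285 in libraries 4 to 6 argue against it as the whole cause. The thalamic neuron score was also higher in intervene there, by 1.06, and its part was not tested. A part played by a larger share stays open, and libraries 1 to 3 do not separate it from a reaction. Without intervene replicate 1, 4 lists passed the permutation test, and without intervene replicate 5, 2 lists.

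The interferon response score was 2.11 ± 0.103 in intervene and 1.51 ± 0.269 in model, with 6 of 6 intervene libraries above all model libraries (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.0952), a difference of 0.48 among libraries 1 to 3 and 0.73 among libraries 4 to 6. Of its 22 measured members 21 had a positive fold change, 0 passed over all genes and 12 adjusted over the list alone. Ifit1, which binds viral RNA, was 6.65 ± 0.862 against 3.54 ± 1.22 CPM, Usp18, a brake on interferon signalling, 1.92 ± 0.326 against 1.05 ± 0.196, and Gbp2, an interferon-induced GTPase, 8.92 ± 4.87 against 3.66 ± 0.932. The glucocorticoid response score was 5.18 ± 0.263 against 5.54 ± 0.144 (exact permutation p = 0.0238, adjusted p = 0.328), a difference of -0.34 among libraries 1 to 3 and -0.38 among libraries 4 to 6. Of other genes with low p, Vasp, an actin regulator, was 14.2 ± 1.46 against 10.3 ± 0.964 CPM, Tlr3 9.48 ± 0.865 against 6.97 ± 0.876, Lcp1, an actin-bundling protein of leukocytes, 16.3 ± 3.27 against 10.5 ± 2.02, and Fancm 4.34 ± 0.319 against 5.47 ± 0.329. The edgeR test called 0 genes, with 531 at an unadjusted p under 0.05; limma-voom called 0 and DESeq2 2.

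Within the 2 sets of replicate numbers this comparison differed. Among libraries 1 to 3 edgeR called 0 genes, with 700 at an unadjusted p under 0.05, while among libraries 4 to 6 it called 675 higher and 378 lower in intervene. There 10 of 14 cytokine and chemokine members, 12 of 20 reactive astrocyte members and 8 of 21 members of the NF-kB and Toll-like receptor list rose. In the same libraries 2 of 5 erythroid members rose, 5 of 5 adjusted over the list alone, the erythroid score was 0.88 higher than in model 4 to 6, and mitochondrial genes took 12.3 to 17.7% of counts against 9.44 to 12%. Ccl2, a monocyte attractant, was 6.47 ± 1.46 CPM in intervene 4 to 6 and 0.605 ± 0.381 in model 4 to 6 (log2 fold change 3.42 ± 0.76, adjusted p = 0.0190). Cxcl10, an interferon-induced chemokine, was 15 ± 7.79 against 0.766 ± 0.733 CPM, Tlr2 6.28 ± 1.28 against 1.24 ± 0.250 and Hmox1 56.7 ± 3.20 against 16.2 ± 9.68, with adjusted p of 0.0209, 0.000266 and 0.00884. In intervene 1 to 3, Ccl2 was 0.360 ± 0.315 CPM, Cxcl10 2.02 ± 1.46, Tlr2 2.37 ± 0.151 and Hmox1 6.44 ± 1.33. In intervene 4 to 6, 8 of 18 thalamic and 4 of 8 habenula members also rose against model 4 to 6, and so did the transcription factor gene Shox2, which is in none of the lists, from 0.401 ± 0.320 to 15.6 ± 3.94 CPM (adjusted p = 0.000191). Prss12 fell from 20.9 ± 5.56 to 7.42 ± 2.39 CPM (adjusted p = 0.0182) and Lars2, whose reads can be shared with ribosomal RNA, from 382 ± 118 to 101 ± 7.33 CPM (adjusted p = 0.00395). The difference between the sets was itself past the threshold for 51 genes in the positive and 14 in the negative direction. It passed a permutation test for 9 of 44 list scores. The intervene minus model difference was larger in libraries 4 to 6 for thalamic neurons (by 1.33), habenula (3.60), neutrophils (1.83), reactive astrocytes (0.99), NF-kB (0.71), coagulation (0.55), haem (0.34) and ribosome biogenesis (0.12), and lower for pericytes and smooth muscle (-0.65), with adjusted p of 0.0425 to 0.0442. For cytokines and chemokines it was 1.61 larger (adjusted p = 0.0516).

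The comparison of intervene with control covers Coll IV and remodelin together. In it 9 of 44 lists rose and 0 fell, all of them lists of glial reaction, inflammation, haem handling or proteases. With an estimated correlation between genes camera called 0 of the 44. Its adjusted p was 0.0669 for reactive astrocytes and 0.190 to 0.197 for the other 8. Camera asks whether a list moved more than other genes, and the permutation test whether its own mean moved. Fry, which asks the latter and also allows for correlation, called these 9 higher, with an adjusted p of 0.000768 to 0.0226. The reactive astrocyte score was 3.12 ± 0.297 in intervene and 1.95 ± 0.293 in control, the interferon response score 2.11 ± 0.103 against 1.54 ± 0.326, the complement score 3.22 ± 0.201 against 2.71 ± 0.113 and the inflammasome and pyroptosis score 1.99 ± 0.127 against 1.69 ± 0.157. For these 4 lists 6 of 6 intervene libraries lay above all controls (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.0238). The gap was narrow for inflammasome, with intervene replicate 1 at 1.884 and control replicate 6 at 1.88. For complement it lay between intervene replicate 1 at 2.933 and control replicate 2 at 2.895. Reactive microglia and macrophages, with 4.38 ± 0.318 against 3.68 ± 0.344, and haem, iron and oxidative defence, with 5.18 ± 0.171 against 4.90 ± 0.08, had an adjusted p of 0.0317. Cytokines and chemokines, with 1.07 ± 1.19 against -0.60 ± 0.28, NF-kB and Toll-like receptor signalling, with 2.44 ± 0.349 against 1.90 ± 0.138, and coagulation, fibrinolysis and matrix proteases, with 3.56 ± 0.137 against 3.22 ± 0.183, had an adjusted p of 0.0423. With labels permuted within libraries 1 to 3 and 4 to 6, 5 of the 9 passed at an adjusted p of 0.0440: reactive astrocytes, with a difference of 0.80 among libraries 1 to 3 and 1.53 among libraries 4 to 6, inflammasome (0.28 and 0.32), interferon (0.60 and 0.54), complement (0.45 and 0.57) and reactive microglia (0.67 and 0.72). The other 4 were cytokines (0.45 and 2.88), NF-kB (0.19 and 0.90), the haem list (0.08 and 0.47) and coagulation (0.21 and 0.48), with an adjusted p of 0.0629 to 0.08. With library totals in place of TMM 2 lists passed and with FPKM plus 1, 0 lists. Without 1 library 4 or 5 passed if it was a control. It was 2 without intervene replicate 2 or 6, 3 without intervene replicate 3 and 8 without intervene replicate 1, 4 or 5. Choroid plexus moved in the same direction as these lists, at 2.82 ± 1.78 against -0.09 ± 1.74 (exact permutation p = 0.0260, adjusted p = 0.114), a difference of 1.45 among libraries 1 to 3 and 4.37 among libraries 4 to 6.

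Over all genes 0 members of these lists passed. Adjusted over the list alone, 14 of 20 reactive astrocyte, 14 of 22 interferon, 13 of 14 cytokine, 8 of 21 NF-kB and 6 of 19 reactive microglia members were higher and 0 lower. Within libraries 1 to 3 these counts were 3, 3, 0, 0 and 4 higher and 0 lower. Within libraries 4 to 6 they were 15, 4, 13, 13 and 7 higher, with 1 reactive microglia member lower. The CPM below are over both sets unless a set is named. For the inflammasome list it was 3 of 12, for coagulation 1 of 12 and for complement 0 of 15, and in the haem list 3 of 21 were higher and 1 lower. Tgm1, a transglutaminase of the reactive astrocyte list, was 2.39 ± 0.940 CPM in intervene and 0.0615 ± 0.0429 in control (log2 fold change 5.20 ± 0.83, adjusted p = 0.0617). Ptx3, a pentraxin, was 2.26 ± 2.22 against 0.168 ± 0.167 CPM and S1pr3, a sphingosine phosphate receptor, 8.78 ± 1.58 against 5.44 ± 0.982. Of the cytokine list, Il1a was 1.98 ± 1.43 against 0.452 ± 0.244 CPM. Of the NF-kB list, Rela, a subunit of NF-kB, was 23.0 ± 4.17 against 16.4 ± 1.41, and the adhesion molecules Icam1 and Vcam1 were 6.37 ± 2.18 against 2.82 ± 1.20 and 29.8 ± 4.19 against 20.7 ± 2.42. Clec7a and Tyrobp of reactive microglia were 2.74 ± 1.10 against 0.553 ± 0.333 and 28.5 ± 3.66 against 21.0 ± 3.09. The complement genes C3 and C1qb were 6.84 ± 4.08 against 1.61 ± 1.37 and 108 ± 24.6 against 84.3 ± 13.1, and the inflammasome genes Casp4 and Pycard 0.924 ± 0.193 against 0.440 ± 0.211 and 3.17 ± 0.566 against 2.04 ± 0.594. Adamts1, a matrix protease, was 10.4 ± 3.13 against 5.32 ± 1.22 and Anxa2 23.7 ± 5.40 against 14.5 ± 6.0. Hmox1 was 31.5 ± 27.6 against 7.28 ± 1.48 CPM, at 56.7 ± 3.20 in intervene 4 to 6 and 6.44 ± 1.33 in intervene 1 to 3.

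Outside the lists, the lowest p belonged to Vasp (14.2 ± 1.46 against 8.91 ± 1.25 CPM, log2 fold change 0.67 ± 0.10, adjusted p = 0.0617), followed among others by the chloride channel gene Clic1 (18.9 ± 2.51 against 12.6 ± 1.00), Lilrb4a, a receptor of myeloid cells (1.65 ± 0.940 against 0.220 ± 0.111), and podoplanin, Pdpn (18.4 ± 3.52 against 10.6 ± 2.31). Among lower genes, Chka, a choline kinase, was 36.6 ± 2.45 against 44.8 ± 2.66 CPM and Kitl 24.7 ± 2.63 against 40.2 ± 14.3. With edgeR 0 genes passed and 1551 had an unadjusted p under 0.05. DESeq2 called 79 genes, 72 higher and 7 lower, and limma-voom called Vasp and Pdpn. DESeq2 left 28855 of 34941 genes without an adjusted p here and 15618 in the other comparisons. Its count was thus adjusted over fewer genes than those of its other comparisons and of edgeR. Without control replicate 2 edgeR called 2 genes and without intervene replicate 1 it called 4. With the set of replicate numbers as a covariate edgeR called 59 higher and 7 lower; within libraries 1 to 3 it called 0, with 1579 at an unadjusted p under 0.05, and within libraries 4 to 6 it called 2713 higher and 2063 lower. In libraries 4 to 6 the region markers differed as well, with 13 of 15 choroid plexus, 11 of 14 hypothalamus and 14 of 18 thalamic members higher in intervene. Of 5 erythroid members 4 were higher too, with a score 1.02 higher in these libraries, 0.06 lower in libraries 1 to 3 and 0.48 higher over all 12 libraries (exact permutation p = 0.0779, adjusted p = 0.229), and mitochondrial genes took 12.3 to 17.7% of counts in intervene 4 to 6 against 7.40 to 11.2% in controls 4 to 6.

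**Figure D2:**
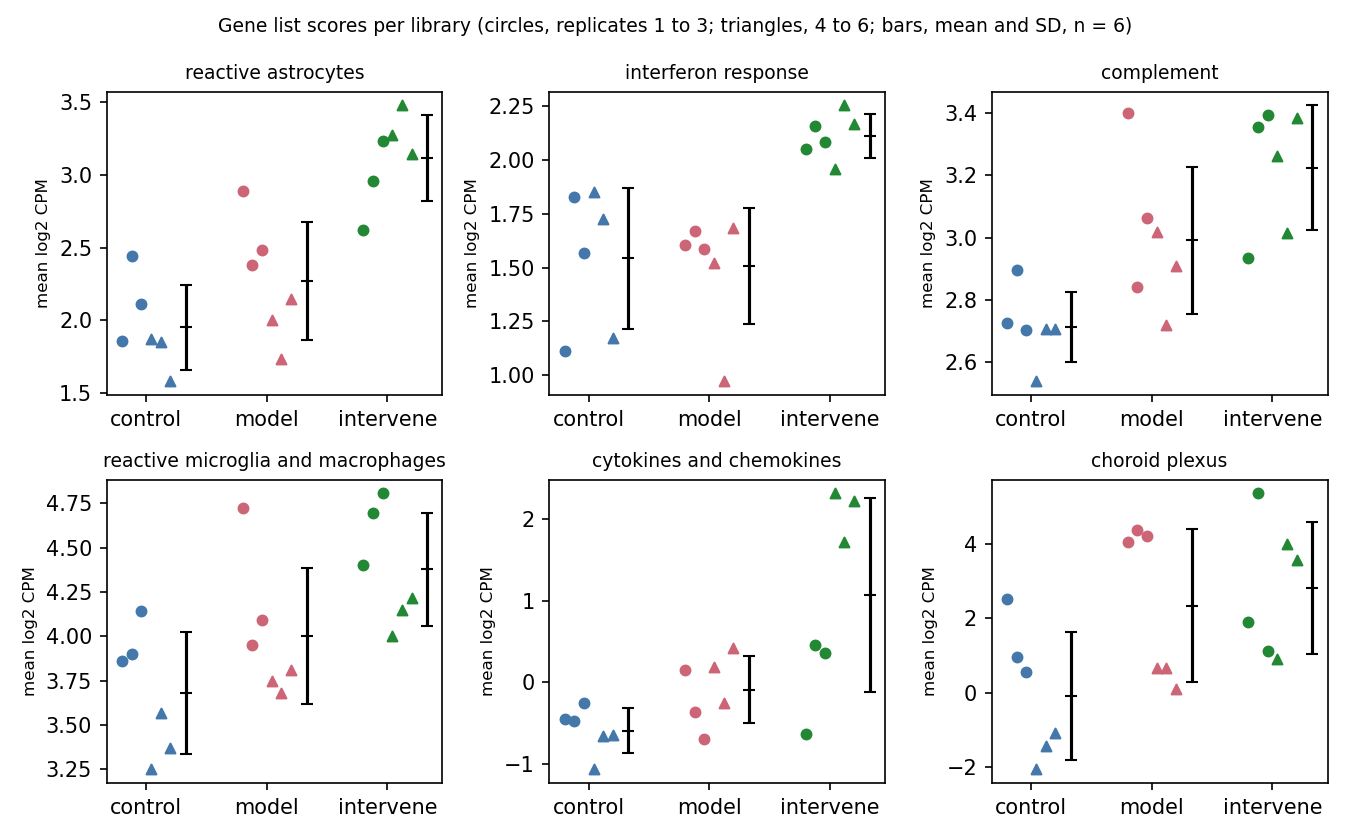
Scores of 6 gene lists (y axes, mean log2 CPM of the measured members) in each library by group, circles for replicates 1 to 3 and triangles for 4 to 6, with the mean and SD (n = 6) beside the points. Cytokine and chemokine scores of intervene triangles run from 1.72 to 2.32 and those of the other 15 libraries from -1.07 to 0.455.

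Since edgeR called 0 genes between model and control, 0 could be followed back toward control in intervene. For the same reason the calls of model and of intervene against control could share only 0 genes. The 0 expected of independent lists and the at most 0 in 20 simulated unchanged sets thus decide nothing about an overlap. Across all 18452 genes, which are not independent replicates, the differences of model minus control and intervene minus model had a correlation of -0.07 and a covariance of -0.00618. Unchanged simulated groups that share the model libraries gave -0.50 and -0.0520. Their libraries were drawn independently, without the division by replicate number or the joint deviations of equal numbers seen in the data. With the model libraries halved the mean correlation over 20 divisions was 0.23, and 38.5% of genes had opposite signs. No division of 6 libraries into 3 and 3 balances libraries 1 to 3 and 4 to 6, so the difference between these sets raises this value and lowers the one with control libraries halved. The differences of model and of intervene from control correlated at 0.68 with a covariance of 0.0794, against 0.49 and 0.0510 in the same simulation; with the control libraries halved the mean values were 0.15 and 0.0117.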

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

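Except for the splits of the 3 group comparisons, the tests in this part were chosen only after the results they bear on had been seen, and those of blood, of brain regions, of an equal effect, of libraries 4 to 6 alone and of thalamus against cortex replaced earlier tests whose outcomes had been seen; of these only the bounds for thalamus against cortex were set before the outcome was seen, and the form of that test within the sets was added once the first was known, with the same bounds and before its own outcome. The test of brain regions is the third one tried, and its bounds were set with the scores of the libraries known. A library stood far from the other 5 of its group in 18 of 294 group values examined; chance gives this in about 1 in 20 groups.

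The total was 118 M counts in control replicate 1, with the next control at 56.9 M. List scores far from the rest were those of fibroblasts and collagen matrix in control replicate 2 (3.77, next 2.82), interferon response in model replicate 5 (0.973, next 1.52), haem, iron and oxidative defence in control replicate 4 (4.75) and model replicate 5 (4.90), and RNA acetylation and methylation factors in model replicate 1 (5.46, next 5.39). Model replicate 1 also had the highest CPM of its group by far for Lgals3 (9.69), Tgm1 (1.41), Clec7a (4.29) and C3 (12.5). Choroid plexus genes stood out in intervene replicate 2, with F5 at 36.5, Kcne2 at 39.1 and Aqp1 at 32.3 CPM, and in control replicate 1, with F5 at 3.49, Kcne2 at 3.26 and Ttr at 688 CPM. Clic1 in control replicate 6 was 14.6 CPM and Anxa2 in control replicate 2 was 25.7 CPM. The intervene minus model difference changed between libraries 1 to 3 and 4 to 6 for 65 genes and the intervene minus control difference for 3305 genes, by a test of the difference itself.

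The genes called were also counted in other splits of the libraries. For the 3 comparisons with 0 genes called, 100 of 100 splits gave as many, which holds for any split and decides nothing about chance; the highest other split called 4387 genes in model against control, 0 in intervene against model and 2127 in intervene against control. Splits that call so many genes point to a structure of the samples. Those with 4387 and 2127 genes put 5 of 6 libraries of 1 set of replicate numbers together, but the sets alone do not account for them: the other 4 such splits drawn for model against control called 0, those for intervene against control 0 in 3 cases and 17 in 1, and all 5 for intervene against model called 0. In model against control, 4 drawn splits that part all 6 pairs of equal replicate number, as the real one does, called at most 0. With the set as a covariate, intervene against control called 66 genes, and 7 of 100 splits within the sets called as many, the highest other 2138, so chance is not excluded. For libraries 4 to 6 alone 10 splits are too few for a share under 0.05: the real split called 1053 genes against model and 4776 against control, and the highest other 1 and 0; in each case 1 split, the real one, reached its count. Between libraries 1 to 3 and 4 to 6 of control and model the real division called 8729 genes, 1 of 100 divisions, the real one, reached that, and the highest other called 5786. That division was taken from the first principal component of the same libraries, so this count restates what was seen and excludes nothing.

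The first pattern weighed is that division. The medians of the cortex and thalamic lists moved apart by 2.92 on the log2 scale, in control and model, as a different share of thalamus and neighbouring regions in the tissue would give. For control and model a batch with equal tissue is argued against by the cortex minus thalamic score, whose lowest value in libraries 4 to 6 lay 0.695 above the highest in libraries 1 to 3; for intervene, where the same value was -0.265 and the scores overlap, such a batch stays open. Depth is argued against as well, since 7508 genes were still called without control replicates 1 and 5. A batch that came together with a different dissection may remain, the labels name neither, and no biological explanation was tested, since the division is not a group of the study.

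The second pattern is the cytokine and chemokine list in intervene libraries 4 to 6. A share of thalamus, cortex or choroid plexus cannot be told apart from the group: 3 other libraries, model replicate 1 and intervene replicates 1 and 2, had a cortex minus thalamic score in the range of these 3 and at least their lowest choroid plexus score, at 4.07, 1.89 and 5.38 (0.914, 4.01 and 3.58 in these 3), with low cytokine scores of 0.149, -0.637 and 0.455, and control replicate 3 matched in the first score only (choroid plexus 0.551, cytokines -0.256), but all are numbered 1 to 3 and no control or model library numbered 4 to 6 matches. Blood left in the tissue cannot be told apart either: 7 other libraries had an erythroid score of at least 4.52, the lowest of these 3, and a lower cytokine score, but they are all numbered 1 to 3, and the score itself was lower in control and model libraries 4 to 6 (3.50 to 4.10), so equal scores need not mean equal blood in both sets. An equal effect of the treatment in all 6 libraries stays open for this list: the intervene minus model difference was 1.61 larger in libraries 4 to 6, with a permutation p of 0.0117 and an adjusted p of 0.0516 over the 44 lists, while edgeR called this difference for 0 of the 14 members; 9 other lists passed the same test at an adjusted p of 0.0425 to 0.0442, among them reactive astrocytes, NF-kB and thalamic neurons. A difference in handling, injury or time between the sets, and an effect of remodelin that depends on them, may both hold, and the labels do not separate them.

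The third pattern is the rise of 9 lists in intervene against control. Of these 0 passed with camera at an estimated correlation, which compares a list with other genes (lowest adjusted p = 0.0669). All 9 passed with fry, which does not (adjusted p of 0.000768 to 0.0226). After adjustment for the cortex minus thalamic score all 9 kept a permutation p under 0.05. Here and in the adjustments below group labels were permuted with the adjusting score held fixed, so these p values are approximate. With the set in the fit and labels permuted within the sets 9 of 9 kept it too, with 85 to 102% of their difference. Cytokines, for example, went from 1.67 ± 0.45 to 1.42 ± 0.33 (SE). This argues against a different share of thalamus and cortex as the whole cause only if such a share acts alike in both sets, as the fit assumes. The score of intervene minus control was 1.27 among libraries 1 to 3, where the groups overlap, and -2.33 among libraries 4 to 6. The sets thus nearly cancel (-0.53 ± 0.99), and the adjustment over all 12 libraries was small. Of the 33 lists outside the 9 and the score, 2 moved by more than their adjusted SE. In libraries 4 to 6 the scores of intervene (1.4 to 2.43) and control (4.03 to 4.41) did not overlap. An effect of such a share in these libraries, in part or as a whole, thus cannot be told apart from the group and stays open. Whether the rise of the 9 lists comes from intervene libraries 4 to 6 alone stays open. Among libraries 1 to 3 all 3 intervene libraries lay above all 3 controls for 5 of the 9 lists. Chance separates 3 from 3 in 10% of cases in either direction. Cytokines, NF-kB, the haem list and coagulation overlapped. After adjustment for the choroid plexus score 3 of the 9, reactive astrocytes, interferon response and complement, kept a p under 0.05, with differences of 1.07, 0.62 and 0.45 after and 1.17, 0.57 and 0.51 before; the other 6 kept 57.8 to 87.0% of their difference and lost the call as it became smaller and its standard error larger, such as cytokines from 1.67 ± 0.50 to 1.45 ± 0.70 and inflammasome from 0.30 ± 0.08 to 0.18 ± 0.10 (SE), so a part played by choroid plexus is neither shown nor excluded. An effect of Coll IV with remodelin is among the open explanations and was not separated from Coll IV alone by this comparison.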

How the results depend on the processing

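The alternatives that use the set of replicate numbers were chosen after seeing the data. For model against control, 0 genes stayed 0 in every setting run except DESeq2 (2 genes). For intervene against model it stayed 0 except with DESeq2 (2) and only libraries 4 to 6 (1053). For intervene against control it became 79 with DESeq2, 2 with limma-voom, 2 with the stricter filter, 1 in the 12 libraries alone, 8 with 1 surrogate variable, 1 with FPKM at either pseudocount, 66 with the set as covariate and 4776 in libraries 4 to 6. Leaving out each library gave 0 to 0, 0 to 0 and 0 to 4 genes; 2 came without control replicate 2 and 4 without intervene replicate 1. With the replicate number as a block the 3 counts were 0, 0 and 0, so this block changed no call of genes. Same-number correlations were -0.14 to 0.38 between intervene and control and -0.13 to 0.35 between intervene and model. There 4 of 12 and 3 of 12 libraries correlated best with their own number, and between model and control 4 of 12. These values do not show a pairing by number.

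The 0 lists of model against control became 12 with camera at a preset correlation of 0.01 (9 higher, 3 lower). Those of intervene against model became 1 with camera at an estimated correlation, 22 at 0.01 (17 higher, 5 lower) and 2 with fry. Leaving out each library gave 0 to 0 and 0 to 4 lists, with 4 without intervene replicate 1 and 2 without intervene replicate 5. The 9 lists of intervene against control became 8 with RLE or upper-quartile scaling or without haemoglobin and mitochondrial genes, 6 with 1 surrogate variable (cytokines, NF-kB and coagulation lost the call, with an adjusted p of 0.0544, 0.0595 and 0.0952), 2 with library totals, 5 without a filter, 2 and 0 with FPKM plus 0.1 and plus 1, 4 with medians, 0 with camera at an estimated correlation, 28 at 0.01, 14 with fry and 5 permuted within sets. They became 0 with the replicate block, where the smallest p is 0.0312 and passes only if most of the 44 lists reach it, and 0 within libraries 1 to 3 or 4 to 6, where the smallest p of 0.1 cannot pass. These say little about stability. The 28 lists of camera at 0.01 were 21 higher and 7 lower, and the 14 of fry 11 higher and 3 lower. Without 1 library 2 to 8 lists passed: 4 without control replicates 1, 4, 5 or 6 and 5 without controls 2 or 3. It was 2 without intervene 2 or 6, 3 without intervene 3 and 8 without intervene 1, 4 or 5. In each of these fits the lowest p was 0.00216, the smallest possible with all libraries too. A limit on the smallest p thus does not explain the lists lost without 1 library. The cause of these and the other changes was not tested. The overlap of calls against control became 1 gene with DESeq2, where 2 genes were called in model and both had the opposite sign in intervene minus model, 0 of them called there. In the other 8 alternatives 0 genes were called in model, so 0 was the only value possible for the return and for the overlap.

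Directions turned for Nat10 in intervene against model, to 0.021 with 1 surrogate variable and 0.010 within libraries 1 to 3, and its value ran from -0.056 without model replicate 2 to 0.030 without model replicate 6, with 0.011 without intervene replicate 2. Within libraries 1 to 3 they turned for Hmox1 against control (-0.068) and, against model, for Shox2 (-0.28), Prss12 (0.056) and Lars2 (0.38); the cause was not tested. Depth limits genes below about 1 CPM, such as Ccl2 in controls.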

Other observations

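Glia and neurons also differed between the sets of replicate numbers. In control and model libraries 4 to 6, 15 of 16 myelinating oligodendrocyte members were lower than in libraries 1 to 3 (median log2 difference -0.87) and 0 higher, and 12 of 12 ependymal members were lower (-1.91). Homeostatic microglia went the other way, with 8 of 12 members higher and 1 lower, while 10 of 19 reactive microglia members were lower. Members of the circadian clock list were higher in 8 of 12 cases (median 0.65) and lower in 0. For the striatum list the groups are given apart: in model 10 of 14 members were higher in libraries 4 to 6 and 0 lower (median 2.40), and in control 0 were higher and 3 lower (median -0.17), while the difference between the groups was itself called for 0 of 14 members.

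In libraries 4 to 6, 7 of 16 myelinating oligodendrocyte members were higher in intervene than in model and 0 lower. Of 12 circadian clock members 3 were lower there, and of 8 glucocorticoid response members 1. The genes for RNA acetylation and methylation factors scored 5.40 ± 0.0423 in intervene, 5.40 ± 0.0345 in model and 5.44 ± 0.0348 in control (SD, n = 6), and 0 of 11 members passed in the comparisons over all 18 libraries.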
